A study of Rattus norvegicus with 14 samples.

How the data were processed

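Skin of male CD hairless rats was measured on 14 one-colour Agilent expression arrays, 1 array per animal, 6 from animals exposed at 94 GHz and 8 from sham animals. The groups were taken from the treatment named in each sample's labels, and animals were numbered within a group only to name them. Per the labels the rats shared cages in pairs. Which animals shared a cage is not given in the sources used here, so cage could not be used as a block and p-values treat animals as independent. Per the labels' protocols, total RNA came from skin biopsies and was labelled with the Cy3 dye by low-input amplification.

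The deposited scanner files hold spot intensity values on a linear scale, and per the file headers they were made with Agilent Feature Extraction 10.7.3.1, which subtracts background from each spot. The processed signal of these files is not scaled between arrays. The authors' deposited table holds log2 values of 15168 probes. Each of its probes is centred on its median over the 14 arrays, and its column medians lie between -0.0086 and 0.012. How the authors normalized it is not given in the sources used here. After the same centring, its columns correlated across probes at 0.995 to 0.999 with quantile-normalized processed signals of the same array and at 0.902 to 0.992 with the 75th percentile scaling, so its direction and log2 scale were settled from the values. Of its probes, 15147 were well above background on all 14 arrays.

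Each array held 62976 spots, of which 4259 were control spots and were left out, together with spots marked as non-uniformity or population outliers. The processed signal was put on the log2 scale, the 75th percentile of each array was subtracted, and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 6 arrays, which left 21014 of 30367 probes. The scanner files used here carry no gene symbols, so probes were named by matching their accession, without version, to a RefSeq gene table of assembly GRCr8. A symbol was found for 17998 probes (59.3%), and other probes kept their accession or probe identifier. A gene was given by its brightest kept probe, which gave 18611 genes, 11315 of them with a symbol. Among the genes named in the text, Hfe, Cdkn1a and Ano1 had 2 kept probes each that differed in direction. The array design and the gene table refer to different assemblies, so no coordinates are given.

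Exposed and sham arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided, Benjamini-Hochberg adjustment over all genes). The score of a gene list in an animal was the mean over its measured members of the log2 value minus the gene's mean over the 14 animals. List scores were compared by a two-sided exact permutation test over all 3003 splits of the animals into 6 and 8, with Benjamini-Hochberg adjustment over 34 lists. A list needed 5 measured members; the B cell and plasma cell list had 3 and was not tested. Intervals of list differences are 95% intervals from the same permutations. Principal components of the gene-centred values were compared by the same permutation test. The spread within groups was compared as the median over genes of the log2 ratio of SDs.

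The 35 lists, the main tests of exposed against sham, most alternatives and the rule for the genes named were fixed before the data were examined. The relations with array signal were chosen after the data were seen. The rule took the 10 genes with a symbol in each direction by adjusted and then unadjusted p, the 2 members with the smallest p of 6 lists on stress, inflammation and dermal matrix, 5 measured genes fixed by name (Hspb1, Hmox1, Cdkn1a, Il1b and Col1a1), and 2 members of any other list with an unadjusted p under 0.05. Hspa1b was also on the rule but had no matched probe here. Genes named outside the rule were chosen after their values were seen or are given as examples of a list.

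Alternatives covered background correction, normalization, the filter on dim probes, flagged spots, the choice of probe, slide, array weights, the variance model, covariates for tissue composition and leaving out each array in turn. Background correction by normexp used the median spot signal in place of the mean, since the files used here hold the median. It added an offset of 50 to each corrected signal, which by construction shrinks the log2 differences of dim spots. The arrays lay on 4 slides, each with a scan of its own. One slide held 2 sham arrays, another 2 exposed arrays, slide 3 held 3 of each group and slide 4 held 1 exposed and 3 sham arrays, so slide was used as a block and the comparison was repeated within slides 3 and 4.

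The whole fit was tested on simulated data with 200 genes changed. When changes were added to the real arrays, 53% of those genes were called at 1.5-fold, 84.5% at 2-fold and 96% at 3-fold. These rates hold for 200 changed genes. The adjusted threshold is harder to pass when fewer genes change, and smaller numbers were not run. The number of arrays limits the precision, and the median 95% interval of a gene reached 0.275 on the log2 scale to each side.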

Results

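Gene expression was measured in the skin of hairless rats after chronic exposure to 94 GHz millimetre waves, which deposit their energy in the outer layers of the skin. Exposure lasted 3 h per day on 3 days per week for 5.5 months in 6 animals, and 8 sham animals served as controls. The comparison asked whether this exposure changed the expression of genes in skin. The 75th percentile of array signal ranged from 804.5 to 1967 scanner units. It was 1500 ± 314 (SD, n = 6) in exposed and 1510 ± 342 (SD, n = 8) in sham arrays (exact permutation test, two-sided, p = 0.954). Values below are log2 signals relative to each array's 75th percentile, and differences are exposed minus sham.

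Skin of exposed and sham animals showed no measured gene past the threshold, among heat shock, stress, inflammatory, epidermal and dermal genes as among all others. Of the 761 genes on the lists, 612 were measured. The small heat shock protein Hspb1 lay at 4.91 ± 0.22 (SD, n = 6) in exposed and 4.95 ± 0.16 (SD, n = 8) in sham skin, a difference of -0.042 with a 95% interval from -0.26 to 0.18. Col1a1, the main chain of type I collagen, differed by -0.16 (95% interval -0.55 to 0.22), and the cytokine Il1b by -0.080 (95% interval -0.43 to 0.27). Hmox1, the inducible heme oxygenase, differed by -0.087 (95% interval -0.46 to 0.29). The cell cycle inhibitor Cdkn1a differed by 0.0077 (95% interval -0.55 to 0.57), with 2 probes of opposite direction. With slide as a block Hspb1 differed by -0.145 and Cdkn1a by -0.0789. Col1a1 differed by -0.000988 within slide 3, by -0.445 within slide 4 and by -0.0287 without exposed animal 3. Signs turned for Hspb1 (0.0338) and Il1b (0.0298) without exposed animal 5, for Hmox1 (0.0481) without exposed animal 3 and for Il1b (0.109) within slide 4. Cdkn1a ranged from -0.0861 to 0.198 with single arrays left out.

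Of 18611 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 642 genes, where 931 were expected by chance. Over 99 other splits of the 14 arrays the median was 687 and the highest count 3851. Other splits were not run in the settings below, so the counts there have no such comparison. The count was 1560 without sham animal 6 and 995 without exposed animal 3. It was 2326 with array weights, which gave sham animal 6 the lowest weight, 1127 and 1033 with muscle and adipocyte or muscle and hair follicle scores as covariates, 1053 with array signal as a covariate and 290 within slide 4. Adding a fold of at least 1.5 left 79 genes, 43 higher and 36 lower in exposed skin. The 95% interval lay within 2-fold for 94.7% of the genes and within 1.5-fold for 80.2%. The balance of higher and lower genes moved both ways with the processing and with single arrays: it was 37 higher and 1 lower of 38 with normexp background correction, 35 and 2 of 37 with normexp and quantile normalization, 28 and 6 of 34 in the authors' values, 52 and 25 of 77 with quantile normalization and 34 and 6 of 40 among probes well above background on all 14 arrays, but 78 and 127 of 205 without a filter on dim probes. It was 19 and 46 without exposed animal 4, 31 and 50 without exposed animal 6, 34 and 52 without sham animal 4 and 31 and 43 without sham animal 5. Without single arrays the count reached 125 (sham animal 2), 122 (exposed animal 1), 120 (exposed animal 2) and 133 (sham animal 8). The looser count was 190 with slide as a block, 196 within slide 3 and 290 within slide 4, each with 0 genes past the adjusted threshold.

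The genes with the smallest p are given as values, since none passed. On the higher side, the histone gene Hist1h2an (NCBI gene 306970) differed by 0.56 ± 0.12 (SE), and the probe was not tested against near-identical histone genes. The kinase gene Sbk1 (NCBI gene 113907) differed by 0.41 ± 0.093 (SE), with every exposed animal above every sham animal. Hfe, a regulator of iron uptake, differed by 0.43 ± 0.12 (SE), with a second probe in the opposite direction and 0.189 for the mean of its probes. Tspan33 differed by 0.53, Eef2kmt by 0.73, Csdc2 by 0.42, Cep57l1 by 0.35, Ice2 by 0.30, Fam161a by 0.27 and Mterf3 by 0.22. On the lower side, the vomeronasal receptor gene Vom1r30 (NCBI gene 494230) differed by -0.38 ± 0.080 (SE) and Ilvbl (NCBI gene 362843) by -0.26 ± 0.062 (SE), both without overlap between the groups. The matrix metalloproteinase gene Mmp11 differed by -0.80 ± 0.22 (SE) and the Notch ligand gene Dll1 by -0.33 ± 0.091 (SE). Cacng2 differed by -0.65, Kcns1 by -0.58, the glucagon receptor gene Gcgr by -0.50, Zfp395 by -0.29 and Kifc3 by -0.27. Sbp differed by -0.71 but was well above background on only 2 of 6 exposed and 7 of 8 sham arrays. All 20 of these genes had the same direction within slide 3 and within slide 4, whose arrays were among those that ranked them. The Mmp11 difference was -0.445 with slide as a block, -0.216 within slide 3, -0.903 within slide 4 and -0.376 with normexp. Of the 20 differences, 1 moved by over 1.5 times with slide as a block, 4 within slide 3 and 5 within slide 4. With the mean of a gene's probes 2 moved (Hfe and Zfp395), and with normexp 12. With normexp Vom1r30 was at -0.181 and Sbp at -0.166, and 0 of the 20 changed sign in these settings. The 12 that moved with normexp were the dimmest, with sham means from -5.38 to -3.59. At such low signals the offset of 50 added with normexp shrinks log2 differences most. Sham means of the others ran from -3.04 to 2.44. Over all genes, 6 had groups without overlap, where chance gives 12.4.

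Among heat shock genes and chaperones, 16 of 26 measured members were higher and 10 lower in exposed skin, and 0 passed over all genes or adjusted over the list alone. The Hsp110 family member Hspa4 differed by 0.18 ± 0.069 (SE) and the co-chaperone Dnaja1 by 0.30 ± 0.16 (SE). Dnaja1 differed by 0.161 within slide 3, by 0.757 within slide 4 and by 0.191 without sham animal 6. The list score differed by 0.046 (95% interval -0.039 to 0.14; exact permutation p = 0.385), by 0.018 in slides 3 and 4 with slide as a block, by -0.031 within slide 3, by 0.115 within slide 4, by 0.0131 without sham animal 6 and by 0.0288 without exposed animal 1. Genes of endoplasmic reticulum stress were split 11 higher to 12 lower. Among them Dnajc3 differed by 0.14 (0.033 within slide 3, 0.379 within slide 4 and 0.0467 without sham animal 6). Herpud1, also of that list, differed by 0.059 (0.0352 without exposed animal 1, 0.0368 without sham animal 7 and 0.0965 within slide 4). The score of this list differed by 0.0098 (95% interval -0.10 to 0.13), by 0.024 with slide as a block and by -0.0067 within slide 3. It was 0.084 within slide 4 and -0.0277 without sham animal 6. Oxidative stress genes were split 11 higher to 15 lower, with the metallothionein Mt2A at 0.31 and the extracellular superoxide dismutase Sod3 at -0.20. Their score differed by -0.014 (95% interval -0.090 to 0.064), by -0.049 with slide as a block, by -0.026 within slide 3, by -0.097 within slide 4 and by 0.0062 without exposed animal 5. For the p53 and DNA damage genes the score differed by 0.00045 (95% interval -0.067 to 0.065), with 11 of 19 members higher, the ribonucleotide reductase subunit Rrm2b at 0.36 and the pro-apoptotic gene Bbc3 at -0.18. Rrm2b was well above background on 4 of 6 exposed and 6 of 8 sham arrays, and differed by 0.0746 with normexp and by 0.208 with slide as a block; Bbc3 differed by -0.0708 within slide 3 and by -0.394 within slide 4. The p53 score differed by -0.016 with slide as a block, by -0.0093 within slide 3 and by -0.029 within slide 4, and took either sign with single arrays left out, from -0.016 to 0.023.

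Inflammatory cytokines and mediators were split 11 higher to 11 lower. The chemokine Ccl3 differed by -0.56 ± 0.31 (SE) and the chemokine Cxcl1 by 0.44 ± 0.26 (SE). Ccl3 differed by -0.847 within slide 3 and by -0.369 without sham animal 4, and Cxcl1 by 0.941 within slide 4 and by 0.264 without exposed animal 1. The score differed by 0.058 (95% interval -0.18 to 0.30), by 0.034 with slide as a block, by -0.029 within slide 3 and by 0.16 within slide 4. It was -0.0242, of the other sign, without exposed animal 1 and 0.0182 without sham animal 3. Of the collagens and dermal matrix genes, 20 of 26 were lower in exposed skin and 0 passed. Elastin (Eln) differed by -0.37 ± 0.15 (SE) and fibulin 1 (Fbln1) by -0.40 ± 0.17 (SE). Eln differed by -0.238 with slide as a block and by -0.192 with the mean of its probes, and Fbln1 by -0.182 within slide 3, by -0.701 within slide 4 and by -0.248 with normexp. Their score differed by -0.087 (95% interval -0.38 to 0.19; exact permutation p = 0.541), by -0.040 with slide as a block, by -0.073 within slide 3, by 0.026 within slide 4 and by 0.0216, of the other sign, without exposed animal 3. Matrix remodelling genes, with Mmp11 the member of smallest p, differed by -0.115 (95% interval -0.33 to 0.097), by -0.028 with slide as a block, by -0.103 within slide 3 and by 0.122, of the other sign, within slide 4. The smallest member p adjusted over the list alone was 0.054 in that list, and no member of the other lists came below it.

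The temperature-sensitive TRP channels were the only list with an unadjusted p under 0.05 over the 14 arrays. All 5 measured members, of 12 listed genes on the array, were lower in exposed skin, and 0 passed by themselves. They were the TRP channels Trpv2, Trpm4, Trpv4 and Trpv3 and the listed gene Ano1, which is not a TRP channel. The calcium-activated chloride channel Ano1 differed by -0.10, with a second probe in the opposite direction and a difference of -0.0181 for the mean of its probes, and Trpv2 by -0.23. The score was -0.066 ± 0.10 (SD, n = 6) in exposed and 0.049 ± 0.049 (SD, n = 8) in sham skin, a difference of -0.115 (95% interval -0.20 to -0.026; exact permutation p = 0.017, adjusted p = 0.577 over 34 lists). It was -0.125 in slides 3 and 4 with slide as a block, -0.135 within slide 3 and -0.104 within slide 4. With slide as a block the exact permutation p was 0.075, and with the mean of a gene's probes the difference was -0.0997 (exact permutation p = 0.0523). Without a filter on dim probes the score also took in listed genes that the filter had left out, so it covers another set of genes. That difference was 0.000802 (exact permutation p = 0.985), close to 0.

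Of the 34 lists, 0 changed in the exact permutation test. Hair follicle genes and hair keratins were higher in exposed skin in 23 of 24 members, with Krt25 of the inner root sheath at a difference of 0.73 ± 0.53 (SE), and their score differed by 0.60 (95% interval -0.62 to 1.81; exact permutation p = 0.284). With slide as a block in slides 3 and 4 that difference was 1.21 (exact permutation p = 0.0625), with labels exchanged within those slides it was 1.18 (exact permutation p = 0.05), and it was 0.85 within slide 3 and 1.93 within slide 4. All 22 skeletal muscle markers were higher on average, among them the muscle creatine kinase Ckm at 1.64 ± 1.38 (SE), and their score differed by 1.22 (95% interval -1.32 to 3.73; exact permutation p = 0.31). The muscle difference was 0.35 with slide as a block, -0.12 within slide 3, 1.28 within slide 4 and 0.473 without exposed animal 2, which had the highest score, 4.44. The hair difference was 0.368 without exposed animal 6 and 0.928 without exposed animal 1. Cell cycle genes differed by 0.073 (95% interval -0.10 to 0.27), by 0.013 within slide 3 and by 0.183 within slide 4. Their difference was 0.015 without sham animal 6, which scored -0.437. With limma's camera and its preset correlation these 3 lists were called, with adjusted p = 1.54e-07 for hair, adjusted p = 7.47e-07 for muscle and adjusted p = 0.00124 for cell cycle. With an estimated correlation none was called, each at adjusted p = 0.928, and fry, which tests whether the genes of a list move on balance one way, called 0.

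**Figure D1:**
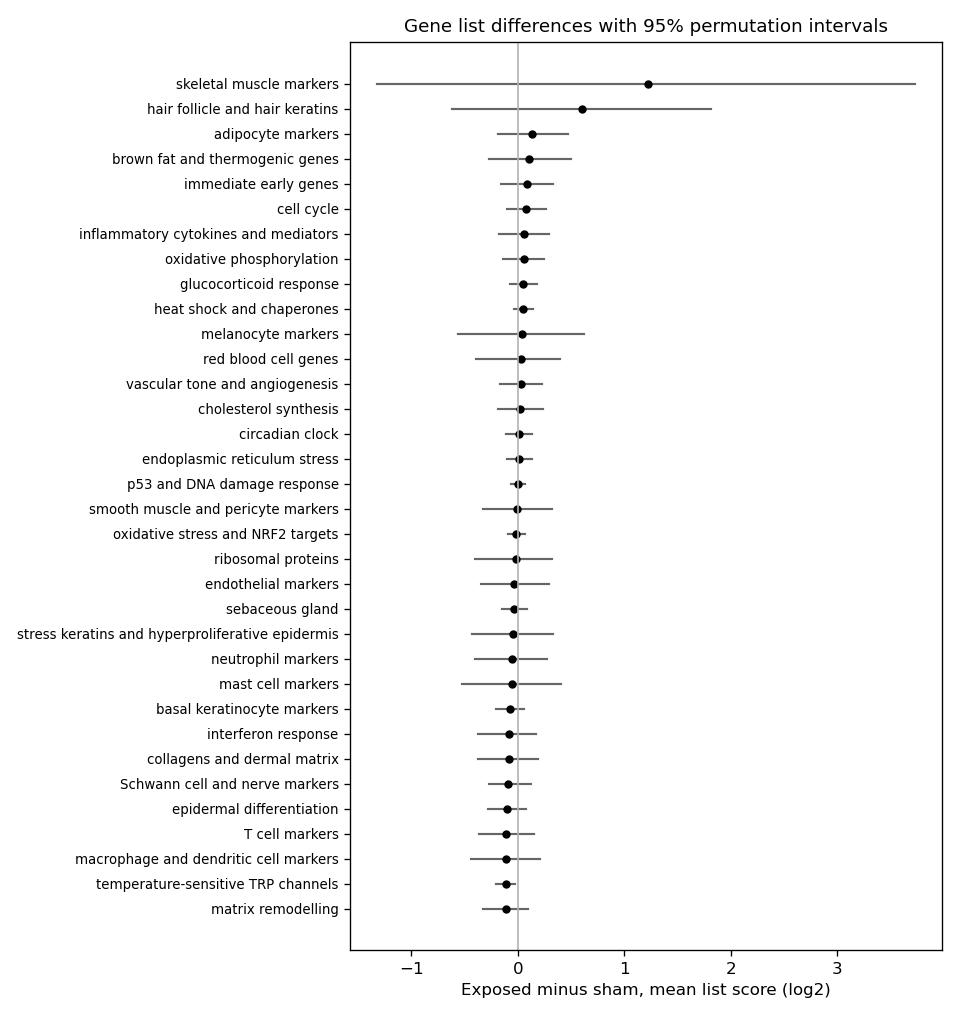
Points give the exposed minus sham difference in mean list score (log2, x axis) for each of the 34 tested gene lists (y axis), and bars give 95% permutation intervals. The TRP channel interval, -0.20 to -0.026, lies below 0, and the muscle interval is the widest, from -1.32 to 3.73.

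The remaining lists describe the cell types and states of the skin. Basal keratinocyte markers, with 8 of 14 listed genes measured, differed by -0.076 (95% interval -0.20 to 0.057), with the basal keratin Krt14 at -0.058. Epidermal differentiation genes differed by -0.10 (95% interval -0.28 to 0.079), with the suprabasal keratin Krt1 at -0.14, and stress keratins by -0.047. Only 18 of 36 listed epidermal differentiation genes were measured, so that score covers a part of the list. For neutrophil markers it was 5 of 11 and for melanocyte markers 6 of 10. Interferon response genes differed by -0.086, T cell markers by -0.11, macrophage and dendritic cell markers by -0.11, mast cell markers by -0.057 and neutrophil markers by -0.057. Adipocyte markers differed by 0.13, brown fat and thermogenic genes by 0.11, sebaceous gland genes by -0.039 and cholesterol synthesis genes by 0.023. Endothelial markers differed by -0.037, smooth muscle and pericyte markers by -0.0099, genes of vascular tone by 0.027, Schwann cell and nerve markers by -0.092, melanocyte markers by 0.043 and red blood cell genes by 0.029. Circadian clock genes differed by 0.012, immediate early genes by 0.090, glucocorticoid response genes by 0.049, oxidative phosphorylation genes by 0.055 and ribosomal protein genes by -0.017. Each of these intervals held 0. Brown fat genes took the other sign with slide as a block (-0.106), within slide 3 (-0.115), within slide 4 (-0.0888) and without exposed animal 2 (-0.0395). The sign also turned with slide as a block for stress keratins (0.0858), mast cell markers (0.0105) and oxidative phosphorylation genes (-0.0183). Within slide 3 it turned for those 3 lists (0.055, 0.133 and -0.00694), for interferon response genes (0.0221), cholesterol synthesis genes (-0.0197), melanocyte markers (-0.0385), immediate early genes (-0.101) and ribosomal protein genes (0.082). Within slide 4 it turned for stress keratins (0.148), oxidative phosphorylation genes (-0.0409), macrophage and dendritic cell markers (0.0494), red blood cell genes (-0.0133) and genes of vascular tone (-0.0299). Over the 34 lists, leaving out 1 array turned the sign of 19, and it turned or moved by over 1.5 times the difference of 31. Among the lists above, interferon response genes turned without sham animal 8 (0.00342), macrophage and dendritic cell markers without exposed animal 3 (0.0132), neutrophil markers without sham animal 1 (0.0396) and endothelial markers without exposed animal 6 (0.00665). Stress keratins turned without exposed animal 1 (0.0813), melanocyte markers without exposed animal 5 (-0.123), mast cell markers without sham animal 8 (0.0454) and ribosomal protein genes without sham animal 6 (0.11), and each of these 4 also turned without at least 1 other animal. Cholesterol synthesis genes, genes of vascular tone, smooth muscle and pericyte markers, red blood cell genes and circadian clock genes also took either sign. Without sham animal 6 the difference was 0.0304 for adipocyte markers and 0.0372 for immediate early genes. Without that animal, basal keratinocyte markers differed by -0.112 (exact permutation p = 0.0338) and Schwann cell and nerve markers by -0.161 (exact permutation p = 0.0239), and without exposed animal 2 sebaceous gland genes differed by -0.093 (exact permutation p = 0.0357), all unadjusted.

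**Figure D2:**
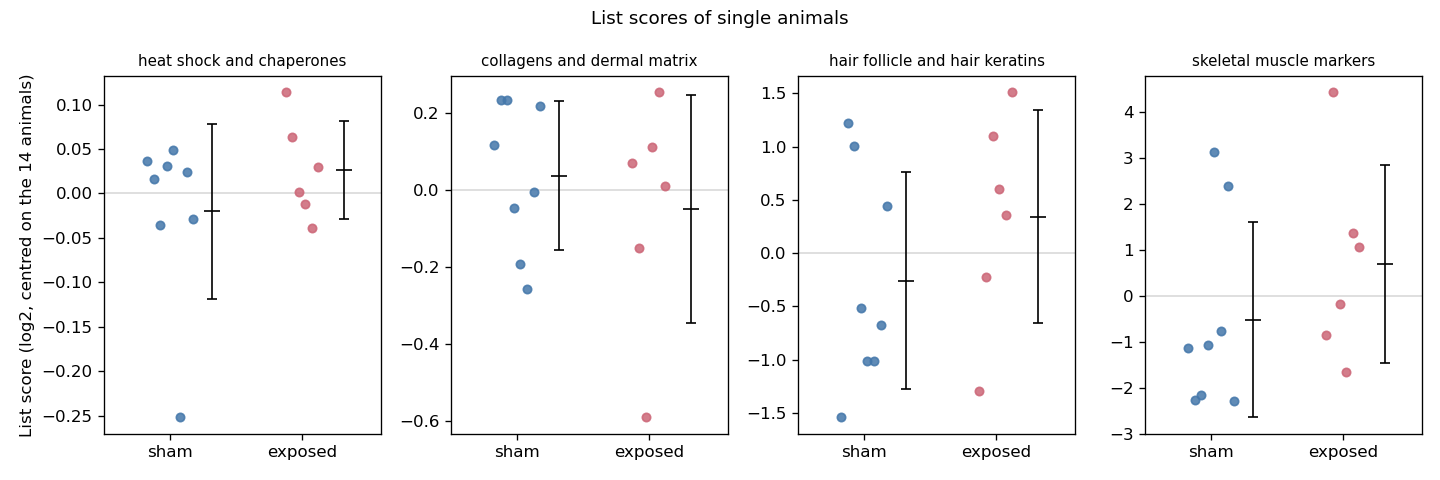
List scores (log2, centred on the 14 animals, y axis; scales differ between panels) of single sham and exposed animals (x axis), with the mean and SD beside each group. Muscle scores ran from -2.30 to 4.44, and the groups overlapped in all 4 panels.

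The main axes of variation between animals were also compared between the groups. Component 1 held 25.5% of the variance and scored 2.82 ± 21.1 (SD, n = 6) in exposed and -2.12 ± 30.8 (SD, n = 8) in sham animals (exact permutation p = 0.79). Components 2 and 3 held 15.7% and 12.9% (exact permutation p = 0.814 and 0.492). Ribosomal protein genes and component 1 both followed array signal. Array signal here is the 75th percentile, which was itself subtracted from every log2 value, so both sides share a term. How much of these relations that sharing gives was not tested. These relations were chosen after the data were seen. The 4 relations tested were picked from the lists and components, and their adjusted p-values do not cover that choice. Component 1 correlated with log2 array signal over the 14 arrays at Pearson r = 0.95 (permutation p = 1e-05, the smallest the permutations can give) and Spearman rho = 0.93 (permutation p = 1e-05), with adjusted p = 2e-05 and 4e-05 over 4 relations. It was r = 0.835 without the 2 arrays farthest in signal and r = 0.902 within slide 3 (n = 6, exact permutation p = 0.0167; rho = 0.829, exact permutation p = 0.0583). The ribosomal protein score correlated at r = -0.956 (permutation p = 1e-05) and rho = -0.938 (permutation p = 2e-05), at r = -0.882 without those 2 arrays and at r = -0.884 within slide 3 (n = 6, exact permutation p = 0.0222; rho = -0.829, exact permutation p = 0.0583). Slide 4 held 4 arrays and the other slides 2 each, too few for a correlation.

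**Figure D3:**
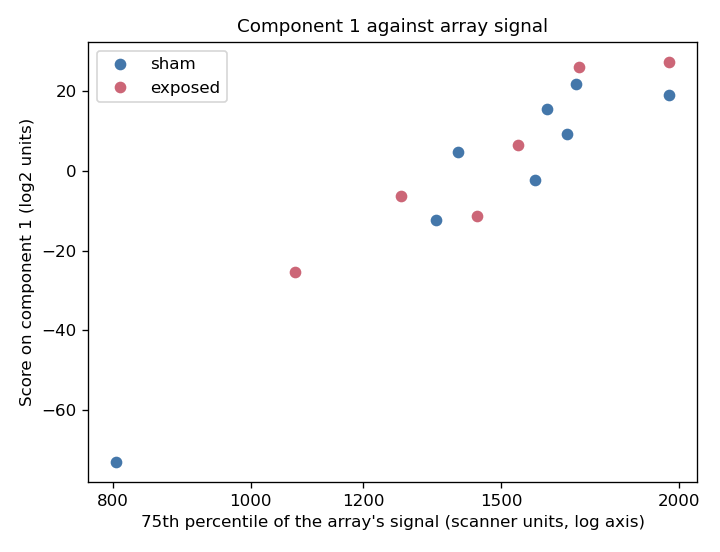
Score on component 1 (log2 units, y axis) against the 75th percentile of the array's signal (scanner units, log axis) for 8 sham and 6 exposed arrays, each point 1 animal. Sham animal 6, at 804.5 units, has the lowest score, -73.0.

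The median log2 ratio of the SD of exposed over that of sham animals was -0.201. Without sham animal 6 it was 0.27, of the other sign.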

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

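The tests of slide, exposure, tissue content and array signal in this part were chosen after the results were seen; the check under quantile normalization was not. An animal was singled out when its gap to the nearest animal of its group was large against the range of that group. Of 158 groups of values examined, 20 met this, where chance gives about 8, and 10 of the 20 belonged to sham animal 6.

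Sham animal 6 scored -73.0 on component 1, with the next sham animal at -12.2. Its list scores were -0.252 for heat shock genes and chaperones, -0.75 for adipocyte markers, -0.725 for endothelial markers, -0.449 for Schwann cell and nerve markers, 0.915 for red blood cell genes, -0.437 for cell cycle genes and 0.899 for ribosomal proteins. Its log2 values were 1.03 for Dnaja1 and -0.0681 for Dnajc3. With quantile normalization in place of the 75th percentile its gap was still 0.593 of the sham range, above the bound for 8 samples, which argues against the scaling as the cause. Component 1 followed array signal at r = 0.835 without the 2 arrays farthest in signal, so a low signal of this array, or a property of its RNA that also lowers signal, may account for its place. No biological explanation was tested for a single sham animal.

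Other animals stood apart from their own group in 1 to 3 values each. Sham animal 1 scored -42.6 on component 3, where the next sham animal was at -10.2 but exposed animal 1 lay at the same end, at -34.3. Exposed animal 1 scored 0.442 for inflammatory cytokines and mediators and -0.559 for red blood cell genes, and its Ccl3 value was -2.37. Sham animal 8 scored 0.663 for interferon response genes, and its Eef2kmt value was -2.62. Exposed animal 2, which had the highest muscle score, scored 0.248 for sebaceous gland genes and 0.79 for brown fat and thermogenic genes. Sham animal 5, with a muscle score of 3.14, scored 0.463 for brown fat genes. Sham animals 2 and 8, with muscle scores of -2.27 and -2.30, scored -0.353 and -0.30. Sham animal 6 went the other way, at 0.203 with a muscle score of -0.763. The brown fat score was not tested apart from muscle content. The Hspa4 value of sham animal 3 was 0.812, and the Hmox1 value of exposed animal 3 was -0.597.

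Skeletal muscle scores ran from -2.30 to 4.44 between animals, with Tnnc2 ranging over 9.26 and Acta1 over 8.16 on the log2 scale. The range within 1 slide reached 78.7% of the whole and the range within 1 group 90.3%, which argues against slide or exposure as the whole cause. The members moved together: component 1 of the list held 95.9% of its variance, and all 22 measured members, 0 of them on another list, correlated with the rest above r = 0.8. Different amounts of muscle beneath the skin in the biopsies are a candidate explanation.

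Hair follicle and hair keratin scores ran from -1.54 to 1.51. The range within 1 slide reached 90.5% of the whole and the range within 1 group 91.8%, which argues against slide and exposure as the whole cause. Over all 14 arrays the range left after a fit on array signal was 102%, which argues against array signal as the whole cause there. The score correlated with signal at r = 0.471 (permutation p = 0.0868) and rho = 0.578 (permutation p = 0.0342, adjusted p = 0.0456). That adjustment covers only the 4 relations picked after the data were seen. The correlation was r = 0.807 without the 2 arrays farthest in signal, sham animal 6 and exposed animal 3. The fit that left 102% kept both. Within slide 3, which holds exposed animal 3, it was r = -0.308 (n = 6, exact permutation p = 0.578) and rho = -0.257 (exact permutation p = 0.658). Exposed animal 3 had a low signal, 1075 units, and a hair score of 1.1. Slide 3 was not run without that animal, so these values cover unlike sets of arrays. The stage of the hair cycle at sampling was not tested and stays open, as does an exposure effect smaller than this spread.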

How the results depend on the processing

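The covariates for array signal and for muscle with hair scores, and the list differences within slide 4, were added after seeing the data. The number of genes changed was 0 under all alternatives run, with 290 (within slide 4) to 2326 (array weights) genes at an unadjusted p under 0.05; limma calls within slide 4 rest on 1 exposed animal. The looser count of 79 (43 higher, 36 lower) was 38 with normexp and the 75th percentile (37 higher, 1 lower), 37 with normexp and quantile normalization (35 and 2), 34 in the authors' values (28 and 6), 77 with quantile normalization (52 and 25), 205 with no filter on dim probes (78 and 127), 40 with probes well above background on all 14 arrays (34 and 6), 190 with slide as a fixed block, 198 in slides 3 and 4 with that block, 196 within slide 3, 290 within slide 4, 130 with array weights, 186 with muscle and adipocyte scores and 209 with muscle and hair follicle scores as covariates. Fewer genes entered with the stricter filter (16514) and more without a filter (26903). The stricter filter took the lower genes from 36 to 6 and the higher from 43 to 34. Most lower genes of the looser count were therefore dim on at least 1 array. The authors' values differ in genes (13677), normalization and centring at once. For the authors' values and the settings other than the filter the cause was not tested. With normexp, the added offset of 50 shrinks differences of dim genes by construction. Normexp was not run without that offset. Leaving out each array in turn gave 65 (19 higher, 46 lower, without exposed animal 4) to 133 genes (70 and 63), with 125 without sham animal 2, 122 without exposed animal 1, 120 without exposed animal 2 and 133 without sham animal 8. The number of lists changed was 0 except for 3 by camera with the preset correlation. A test within slide 3 or slide 4 cannot reach an exact permutation p under 0.05. Slides 3 and 4 together allow 80 splits, too few for a list by itself to pass the adjustment over 34 lists. The component 1 difference of 4.94 ranged from 3.14 to 6.65 over the processing alternatives and from -1.31 to 9.85 with arrays left out. The SD ratio of -0.201 ranged from -0.26 to -0.184 and, with arrays left out, from -0.398 to 0.27, the latter without sham animal 6. In 15 values of named genes and lists the sign turned by more than the SE of the main difference. Other sign turns, some given above, moved by less. The TRP score turned without a filter (0.000802), where it covers more genes. Brown fat genes turned in slides 3 and 4 with the block (-0.106), with labels exchanged within those slides (-0.114), within slide 3 (-0.115) and within slide 4 (-0.0888). Heat shock (-0.0309), muscle (-0.116) and immediate early genes (-0.101) turned within slide 3. Matrix remodelling (0.122), stress keratins (0.148), oxidative phosphorylation (-0.0409), Cdkn1a (-0.414) and Il1b (0.109) turned within slide 4. Il1b also turned with array weights (0.112), and Col1a1 with muscle and hair covariates (0.0309). Causes of these turns were not tested. None of these values passed a threshold. Of 2152 values of named genes and lists, 122 changed sign, most by less than their error. No paired analysis was possible because animal numbers only follow the order of the samples and pair no animals. Probes near background limit what can be seen of dim genes.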

Other observations

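The families, the keratin groupings and the split by slide 3 in this part were chosen after the data were seen. Keratin-associated proteins, which crosslink hair keratins, were not among the fixed lists. Of 15 measured genes of the family, 13 were higher and 2 lower in exposed skin, with scores of 0.304 ± 1.26 (SD, n = 6) in exposed and -0.228 ± 0.901 (SD, n = 8) in sham animals, a difference of 0.532 (exact permutation p = 0.367). The family followed the hair follicle list from animal to animal, at r = 0.953 and rho = 0.925 over the 14 arrays (permutation p = 1e-05 for each, the smallest the permutations can give), r = 0.937 without the 2 farthest animals and r = 0.965 within slide 3 (n = 6, exact permutation p = 0.00556; rho = 0.943, exact permutation p = 0.0167).

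Scores of keratins of the hair shaft and of the inner root sheath correlated over the 14 arrays at r = 0.746 (permutation p = 0.0026) and rho = 0.776 (permutation p = 0.00154), and at r = 0.859 without the 2 farthest animals. Within slide 3 the relation did not pass, at r = 0.349 (n = 6, exact permutation p = 0.481) and rho = 0.429 (exact permutation p = 0.419). Exposed animal 3 scored 2.66 for 7 shaft keratins and 0.00252 for 6 inner root sheath keratins, while exposed animal 4 scored -0.0213 and 1.48. Sham animal 1 was low in both, at -2.18 and -1.82, and exposed animal 6 high in both, at 1.80 and 1.97. Between the groups, shaft keratins differed by 0.517 (exact permutation p = 0.555) and inner root sheath keratins by 0.793 (exact permutation p = 0.24).

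The counts of the comparison were set against 100 splits of the 14 arrays into groups of 6 and 8, the real one included. For the number of genes changed this says nothing about chance: the real count of 0 is the lowest possible, so all 100 splits reach it, and the highest other count was 1. At an unadjusted p under 0.05 with a fold of at least 1.5, 63 splits gave at least 79 genes, and the highest other count was 523. At an unadjusted p under 0.05 alone, 53 splits gave at least 642 genes. The highest other count was 3851, several times the real one, and what sets that split apart was not examined. The ratio of SDs was as far from 0 in 90 splits, with 0.612 the farthest other value. By camera with its preset correlation, 99 splits called at least 3 lists and the highest other count was 18. Chance cannot be excluded for the other 4 results. The split of slide 3 against the other slides gave 0 changed genes, 681 at an unadjusted p under 0.05, 144 at the looser threshold and 10 lists by camera, the last 3 above the real split. Of the 99 drawn splits, 50, 28 and 40 gave at least as many, so these counts do not set the slide 3 split apart. With slide as a block the looser count of the real split was 190. The drawn splits were fitted without a block, so that count cannot be set against theirs.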
